A study of Mus musculus with 9 samples.

How the data were processed

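Gene expression was measured in 9 samples of mouse embryonic fibroblasts, each hybridised to an array whose probe sets carry Affymetrix-style identifiers. Per the labels, total RNA was extracted with a Qiagen kit and biotin-labelled by the manufacturer's protocol. The labels put 3 samples in each of 3 groups, which are cells with a hairpin against GFP (shGFP), cells with a hairpin against Foxk1 (shFoxk1), and cells with the Foxk1 hairpin plus Foxk1 added back (rescue). The name of the array design, the probe sequences and the extent of the Foxk1 sequence that was added back are not given in the sources used here.

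The authors deposited 1 value per probe set and array, a log2 expression value made with RMA in the affy package, per the submitters' processing notes, with versions not given in the sources used here. RMA corrects the background, makes the distributions of all arrays alike and summarises the probes of a probe set, so differences in total RNA between samples are removed by construction. The authors' deposited tables also give 2 comparisons, shFoxk1 with shGFP (named WT there) and rescue with shFoxk1. Per the file headers, these tables hold a log2 fold change, a p-value and an adjusted p-value for each probe set. The remaining statistics in the authors' deposited tables are t and B, each a score without a fixed range, per the file headers. The tool behind those tables is not given in the sources used here. The authors' deposited table for shFoxk1 and shGFP lists 1238 probe sets at an adjusted p-value under 0.05, and the authors' deposited table for rescue and shFoxk1 lists 170. The limma fit described next, run on all probe sets, called 1238 and 170, and its p-values differed from those of the authors' deposited tables by at most 1.23e-07 and 1.02e-07 on the log10 scale.

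Of 45101 probe sets, 64 were array controls. Symbols came from the authors' deposited tables, where 38089 of the other probe sets have 1 gene symbol, 6948 have none and 0 have several. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, used for names only. That table held the identifier of 35121 named probe sets and not of 2968, which kept their symbol. It renewed the symbols of 1035 genes. Each gene was represented by its brightest probe set, the one with the highest mean over all 9 arrays, which gave 20672 genes, 9652 of them with more than 1 probe set. Unnamed probe sets and the dimmer probe sets of each gene entered no comparison and are described separately. Names of probe sets ending in _x_at or _s_at mark probes that can match more than 1 transcript, and 16 of the 149 named genes rest on such a probe set. For 1 named gene, Timp3, another probe set was called in the opposite direction, in rescue against shGFP.

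Differences were tested with limma 3.58.1 in R 4.3.3. A mean per group was fitted over all 9 arrays without covariates, which leaves 6 residual degrees of freedom. Variances were moderated with eBayes (4.46 prior degrees of freedom), tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 20672 genes. A gene was called at an adjusted p under 0.05, with no minimum fold and no filter on low values. Changes are differences of mean log2 values, given with the standard error (SE) of the fit; levels are means ± SD of 3 arrays. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and the median SE of a change was 0.0642.

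The 30 gene lists and 10 cell type marker lists were written from textbook knowledge, and the comparisons, alternatives and rule for named genes were fixed with them before the data were examined. Lists were tested with camera, a test of whether the members lie higher or lower than the other genes, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the 40 lists of a comparison. Camera with a correlation estimated for each list and fry, which asks whether the members move one way without reference to other genes, were alternatives. The estimated correlation left 2, 2 and 3 lists called in shFoxk1 against shGFP, rescue against shFoxk1 and rescue against shGFP. Median, mean and test differed in sign for 8, 7 and 10 lists, and 0 of these were called. Members were counted as called over all genes and as adjusted over the list alone.

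The rule for named genes took Foxk1 and Foxk2, and for each comparison the 10 largest rises and 10 largest falls among called genes. Such genes had all 3 arrays of the higher group above all 3 of the lower, and a mean in the higher group at or above 6.562, the median level of all genes. Symbols of predicted genes and cDNA clones were left out. The rule also took the 4 members with the smallest adjusted p of each called list, and of the glycolysis and HIF1 lists in each comparison. From the genes that changed in the knockdown and turned back, it took the 6 largest rises and 6 largest falls, and from each called marker list the 2 most abundant members.

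The knockdown and the rescue comparison share the shFoxk1 arrays, which pushes their fold changes in opposite directions by chance. Counts of reversed genes were therefore set beside 20 simulations that kept the called knockdown changes and placed the called rescue changes on random genes. The correlation was set beside 100 simulations of unchanged groups. All of these drew noise independently for each array, so they left out the pairing of replicate numbers described next. Samples with the same replicate number deviated together. The correlation of their residuals over genes was 0.129, 0.147 and 0.0705 for shFoxk1 with shGFP, 0.230, 0.137 and 0.126 for rescue with shFoxk1, and 0.188, 0.126 and 0.0598 for rescue with shGFP. Each sample correlated best with its own number, and of 36 arrangements of the numbers none other reached the real sum (exact permutation p = 0.0278, one-sided, the smallest possible). For the RNA spike-ins the exact permutation p was 0.0833. By the threshold of 0.1 set for all pairs, the numbers paired the samples of rescue and shFoxk1 only, and the labels do not say what a number marks.

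The steps were tested on simulated data made from the spread of shFoxk1 and shGFP over 20672 genes, with 200 genes changed in each of 10 simulations. The fit called 32.4% of genes changed by 0.25 on the log2 scale, 97.5% of those changed by 0.5 and 100% of those changed by 1, and 5.31% of all calls fell on unchanged genes. A list of 30 members shifted by 0.1 had a camera p under 0.05, not adjusted over lists, in 10 of 10 simulations, and 0 unshifted lists did. Genes were simulated independently, so this does not test the list step where members are correlated. Arrays were checked for identical values, and 0 pairs were found. Some probe sets have the same deposited value on all 3 arrays of a group, among them those of Slc7a11 in shFoxk1 and Bmp4 in rescue. The knockdown and rescue against shGFP share the shGFP arrays, which pushes their changes the same way, so 20 simulations in which every called knockdown change returned in full were set beside them.

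The alternatives were a replicate block, each array left out in turn, a filter on genes below the median level, all probe sets tested, the mean of a gene's probe sets, quantile normalization on top, median centring, eBayes with trend and robust settings, array weights, a minimum change of 1 on the log2 scale, and only the 6 arrays compared. Leaving out probe sets ending in _x_at or _s_at, and median centring for the lists, were added after seeing the data. Where the brightest probe set was left out, a dimmer one of the same gene took its place. A different value there need not come from a match to other transcripts. No genome came with the series, so no positions are given. Some results were left out because they are withheld for evaluation.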

Results

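Gene expression was profiled in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos. The control cells carried a short hairpin RNA against GFP, a jellyfish protein that mouse cells do not make (shGFP, n = 3). A second set carried a hairpin against Foxk1, a forkhead transcription factor (shFoxk1, n = 3), and another set carried the same hairpin with Foxk1 added back (rescue, n = 3). Each of the 9 samples was measured on 1 array as log2 values of 45101 probe sets. Array medians lay between 5.92 and 5.95, and arrays of the same group correlated at 0.998 to 0.999 across genes. The leading principal components of the 9 arrays held 28.3% and 23.3% of the variance. The first set the shGFP arrays (scores of -11.7 to -10.6) apart from all arrays with the hairpin (4.01 to 8.86). The 3′ minus 5′ difference of the actin control probe sets, a sign of RNA length, lay between 0.21 and 0.30 on all arrays.

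Foxk1 itself was examined to check the labels. Its brightest probe set had a mean log2 level of 8.94 ± 0.05 (SD, n = 3) in shGFP and 7.82 ± 0.12 in shFoxk1. Foxk1 fell by 1.12 (SE 0.08, adjusted p = 5.18e-05), to 46.0% of the control level, and every shFoxk1 array lay below every shGFP array. In rescue the level was 7.86 ± 0.16, a difference from shFoxk1 of 0.04 (adjusted p = 0.869) that turned to -0.05 without rescue replicate 1, so no return of Foxk1 was seen with this probe set. The dimmer Foxk1 probe sets differed by -0.25 (adjusted p = 0.273 over all probe sets) and -0.10 (adjusted p = 0.540) between shFoxk1 and shGFP, and by 0.09 (adjusted p = 0.734) and 0.17 (adjusted p = 0.339) between rescue and shFoxk1, the latter with all 3 rescue arrays above all 3 shFoxk1 arrays. Their mean levels in shGFP, 5.37 and 4.91, lay below the median of every array, so they can say little about a fall or a return of Foxk1. A probe set outside the added-back sequence cannot see it, and the positions of these probes are not given in the sources used here, so the arrays do not check the label of the rescue samples. Foxk2, the closest relative of Foxk1, stood at 10.83 ± 0.02, 10.77 ± 0.10 and 10.77 ± 0.03 in shGFP, shFoxk1 and rescue, with adjusted p = 0.706 for the knockdown.

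**Figure D1:**
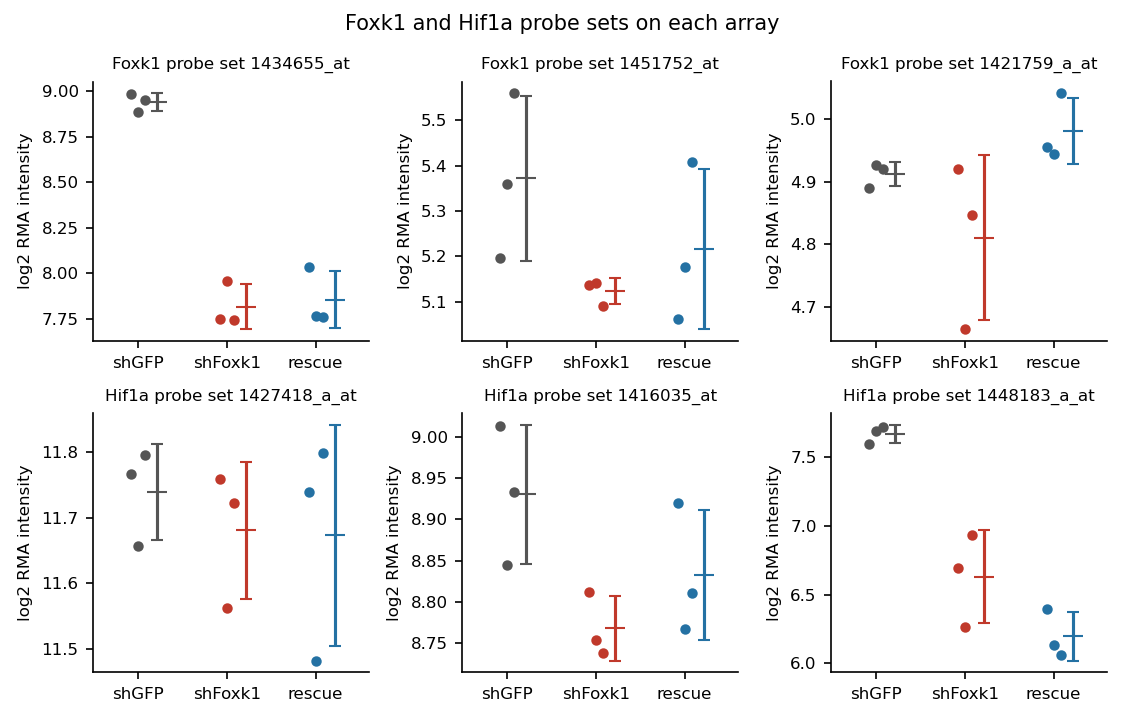
Log2 level of 3 Foxk1 and 3 Hif1a probe sets, a panel each, in the shGFP, shFoxk1 and rescue groups; points are arrays and bars the mean ± SD of 3. The brightest Foxk1 probe set stood at 8.94 in shGFP, 7.82 in shFoxk1 and 7.86 in rescue, and a dimmer Hif1a probe set, shown after its values were seen, at 7.67, 6.63 and 6.20.

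The comparison of shFoxk1 with shGFP asks which transcripts changed when Foxk1 was knocked down. The largest rises were in Ptx3, which encodes a secreted pentraxin (1.54, SE 0.12, 2.90-fold, adjusted p = 5.72e-05), Selenop, a selenium carrier (1.35, SE 0.07, adjusted p = 7.68e-06), Ptgis, prostacyclin synthase (1.29, SE 0.05, adjusted p = 1.89e-06), and Bmp4, a growth factor (1.23, SE 0.08, adjusted p = 2.38e-05). The largest falls were in Ccnd2, which encodes cyclin D2 (-1.59, SE 0.06, 3.01-fold lower, adjusted p = 1.89e-06), Olfm1 (-1.55, SE 0.08, 2.93-fold lower), Sema5a (-1.36, SE 0.10) and Hmox1, heme oxygenase 1 (-1.19, SE 0.07). Armcx4 (1.22), Thbs2 (1.12), the imprinted non-coding RNA H19 (1.07), Map3k5 (1.04) and Sbsn (0.99) also rose. Plcg2 (-0.96), the growth factor Ereg (-0.91), the peptide hormone Adm (-0.88), the cytokine Lif (-0.87) and Fhod3 (-0.86) fell as well. Nfatc4 was called at 1.06 on a probe set that can match other transcripts, and was -0.02 when such probe sets were left out. In all, limma called 876 of 20672 genes (4.24%), 408 higher and 468 lower, with a median size of 0.32 and 16 genes changed at least 2-fold. All 3 arrays of each group stood apart for 22.0% of genes, where chance gives 10%. Among 17417 dimmer probe sets of genes that have several, 294 were called although the gene's brightest was not, 225 of them lower in shFoxk1. The count of 876 fell to 557, 460 and 499 without shGFP replicates 1, 2 and 3 and to 468 without shFoxk1 replicate 1. It was 1501 with a filter on low values, 1530 with trend and robust variance estimates and 1541 with array weights.

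Among 28 inflammatory chemokines and NF-kB targets, 15 fell, 1 rose and 12 did not pass, and 18 fell and 1 rose when adjusted over the list alone (median -0.28, camera adjusted p = 5.44e-14). Cxcl1 (-0.80), Lif (-0.87) and the monocyte chemokine genes Ccl2 and Ccl7 (-0.55 each) were among those that fell. The member that rose was Cxcl12 (0.52), a chemokine gene singled out after its values were seen. Of 36 genes of the ATF4 amino acid response, 10 fell, 0 rose and 26 did not pass, with 16 lower when adjusted over the list alone (median -0.12, adjusted p = 2.70e-12). They included the stress sensor Sesn2 (-0.64), the serine synthesis enzyme Psph (-0.41), Chac1 (-0.39) and asparagine synthetase Asns (-0.28). Cholesterol synthesis genes fell in 8 of 24 cases with 16 not past the test, and in 11 when adjusted over the list alone (median -0.16, adjusted p = 1.53e-09). Among them was Cyp51 (-0.33), and the list's adjusted p = 0.1004 with an estimated correlation. Fatty acid synthesis genes fell in 6 of 21 cases with 15 not past the test, and in 8 when adjusted over the list alone (median -0.11, adjusted p = 5.45e-06, adjusted p = 0.0891 with an estimated correlation). The desaturase Scd1 (-0.28) lost its call without shGFP replicate 1 (adjusted p = 0.0511) or 3 (0.0521). The elongase Elovl6 (-0.25) lost it without shGFP replicate 2 (0.0514) or 3 (0.0618) or shFoxk1 replicate 1 (0.0587) or 3 (0.0530), and was -0.12 as the mean of its probe sets.

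HIF1 targets outside glycolysis fell in 9 of 29 cases, rose in 2 and did not pass in 18, with 14 lower and 3 higher when adjusted over the list alone (median -0.13, adjusted p = 0.00104, adjusted p = 0.497 with an estimated correlation). Adm (-0.88), Bhlhe40 (-0.54) and Stc2 (-0.38) fell, while the collagen cross-linking enzyme Lox (0.52) and Mxi1 (0.28) rose. Mxi1, named after its values were seen, lost its call without shGFP replicate 2 (adjusted p = 0.0623) or shFoxk1 replicate 1 (0.0617) and as the mean of its probe sets (0.150). The list had adjusted p = 0.0539 with fry. Of 23 glycolysis genes, 2 fell, 0 rose and 21 did not pass, and 2 were lower when adjusted over the list alone (median -0.04, adjusted p = 0.0494, adjusted p = 0.465 with an estimated correlation). These were the glucose transporter Slc2a1 (-0.27), which lost its call without shGFP replicate 1 (adjusted p = 0.0937) or 3 (0.0708) or shFoxk1 replicate 2 (0.0773) or 3 (0.0939), and hexokinase Hk2 (-0.25), which lost it without shGFP replicate 1 (0.138) or 3 (0.124), shFoxk1 replicate 1 (0.0544), 2 (0.0883) or 3 (0.138) or rescue replicate 1 (0.0501) or 3 (0.0670). The glycolysis list lost its call without shGFP replicate 3 (adjusted p = 0.167), shFoxk1 replicate 1 (0.0667) or 3 (0.162) or rescue replicate 2 (0.0572), with fry (0.07998) and with the filter on low values (0.0917). Immediate early genes fell in 7 of 25 cases, rose in 1 and did not pass in 17, with 9 lower and 2 higher when adjusted over the list alone (median -0.03, adjusted p = 0.00735, adjusted p = 0.0979 with an estimated correlation). Ier3 (-0.53), Fosl1 (-0.39) and Nr4a1 (-0.32) fell. The member called higher was Etv5 (0.25), named after its values were seen, with this sign in 1 of its 3 probe sets and -0.023 as their mean. It lost its call without shGFP replicate 2 (adjusted p = 0.0704) or shFoxk1 replicate 1 (0.0536) or 3 (0.0512). None of the 30 ribosome biogenesis genes passed, over all genes or adjusted over the list alone, though the list lay low (median -0.03, adjusted p = 0.0141, adjusted p = 0.0979 with an estimated correlation). In the lysosome list, Npc1 (-0.26) fell and 34 of 35 members did not pass, with 5 lower and 1 higher when adjusted over the list alone (median -0.05, adjusted p = 0.0232, adjusted p = 0.497 with an estimated correlation). Npc1 lost its call without shGFP replicate 1 (adjusted p = 0.125), 2 (0.110) or 3 (0.0543), shFoxk1 replicate 1 (0.147) or 3 (0.0951) or rescue replicate 3 (0.0584), and with the replicate number as a block (0.0582). With only the 6 arrays compared, the calls of Slc2a1 (adjusted p = 0.0558), Hk2 (0.0713) and Npc1 (0.0578) were lost, and with all probe sets tested that of Hk2 (0.0538). The lysosome list lost its call without shFoxk1 replicate 3 (adjusted p = 0.209), with fry (0.103), with the filter on low values (0.140) and without probe sets ending in _x_at or _s_at (0.0573).

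Genes of DNA replication and the G1/S transition lay higher in shFoxk1, with 3 of 33 called, 30 not past the test, and 11 higher and 1 lower when adjusted over the list alone (median 0.10, adjusted p = 2.98e-07, adjusted p = 0.0845 with an estimated correlation). Rpa2 (0.24) lost its call without shGFP replicate 3 (adjusted p = 0.0506) or shFoxk1 replicate 1 (0.0522), and the helicase subunit Mcm4 (0.23) without shGFP replicate 2 (0.0653) or shFoxk1 replicate 1 (0.0697). Of 20 FoxO and atrophy targets, 2 rose and 18 did not pass, with 6 higher when adjusted over the list alone (median 0.14, adjusted p = 0.000803, adjusted p = 0.133 with an estimated correlation). Cited2 rose by 0.37, and Pik3ip1 by 0.42 with its call lost without shGFP replicate 1 (adjusted p = 0.0585) or shFoxk1 replicate 1 (0.0602) or 2 (0.0535). As the mean of all probe sets of a gene, Pik3ip1 (adjusted p = 0.229), Rpa2 (0.0661) and Mcm4 (0.0797) were not called. HOX genes rose in 5 of 32 cases and 27 did not pass, with 8 higher when adjusted over the list alone (median 0.05, adjusted p = 0.00407, adjusted p = 0.0864 with an estimated correlation), among them Hoxb6 (0.46), Hoxa9 (0.36) and Hoxb2 (0.29). Contractile and myofibroblast genes rose in 4 of 21 cases, fell in 1 and did not pass in 16, with 7 higher and 2 lower when adjusted over the list alone (median 0.09, adjusted p = 0.00735, adjusted p = 0.133 with an estimated correlation). Tagln (0.87) and the myosin light chain Myl9 (0.58) rose, and Smtn (-0.40) fell. Smooth muscle actin Acta2 rose by 0.85 on a probe set that can match other transcripts, and was -0.13 without such probe sets, where the list had adjusted p = 0.125. With the filter on low values it had adjusted p = 0.0539. TGF-beta and YAP targets rose in 5 of 25 cases, fell in 3 and did not pass in 17, with 8 higher and 4 lower when adjusted over the list alone (median 0.08, adjusted p = 0.00922, adjusted p = 0.0979 with an estimated correlation). The BMP-responsive Id2 (0.71) and Id3 (0.42), Fstl1 (0.66) and Ccn2 (0.35) rose, and Bambi (-0.27) and Pmepa1 (-0.27) fell. Ccn2, Bambi and Pmepa1 were named here after their values were seen, and Pmepa1 lost its call without shGFP replicate 1 (adjusted p = 0.101), 2 (0.135) or 3 (0.0735), shFoxk1 replicate 1 (0.0991), 2 (0.0878) or 3 (0.0891) or rescue replicate 3 (0.0548). None of 33 mitosis genes and none of 27 pentose phosphate and nucleotide synthesis genes passed, over all genes or adjusted over the list alone. Both lists lay higher (medians 0.08 and 0.05, adjusted p = 0.00922 and adjusted p = 0.0318), with adjusted p = 0.279 and adjusted p = 0.554 with an estimated correlation. The nucleotide list lost its call without shGFP replicate 1 (adjusted p = 0.0512) or shFoxk1 replicate 1 (0.0519) or 2 (0.154), with fry (0.0539), with the filter on low values (0.0870) and without probe sets ending in _x_at or _s_at (0.176). Of 40 lists, 16 were called in this comparison, and of the cell type marker lists none was, the lowest being macrophage and blood cell markers (adjusted p = 0.125).

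The comparison of rescue with shFoxk1 asks what adding Foxk1 back changed in cells with the hairpin. Genes known as targets of the hypoxia factor HIF1 led the rises, among them Adm (1.17, SE 0.12, 2.25-fold, adjusted p = 0.00164), carbonic anhydrase Car9 (1.13, SE 0.10, adjusted p = 0.00078), the mitophagy receptor Bnip3 (1.03, SE 0.08, adjusted p = 0.000272), Ndrg1 (1.00, SE 0.11) and Ankrd37 (0.86, SE 0.08). Lrrc17 (0.80), Ccng2 (0.79), Rgcc (0.74, adjusted p = 0.0521 with only the 6 arrays compared), the prolyl hydroxylase Egln3 (0.73) and phosphoglucomutase Pgm1 (0.67) rose too. The largest falls were in Cd24a (-1.04, SE 0.07, 2.06-fold lower, adjusted p = 0.000135), Mn1 (-0.91, SE 0.09), Bmp4 (-0.83, SE 0.08, with the same value on all 3 rescue arrays) and the cell cycle inhibitor Cdkn1c (-0.79, SE 0.06). Tagln (-0.71), the secreted matrix protein gene Ccn2 (-0.69), Akap12 (-0.60), Gas6 (-0.59) and Myl9 (-0.59) fell also. Rescue replicate 2 stood apart from the other rescue arrays, with a score of -14.9 on the second principal component against 0.57 and -4.15 and the narrowest interquartile range of the 9 arrays (3.66). In all, 197 genes were called (0.953%), 135 higher and 62 lower, with 5 changed at least 2-fold. Groups stood apart for 15.6% of genes, where chance gives 10%. The count was 74 and 80 without shFoxk1 replicates 1 and 3, 105 without rescue replicate 2 or 3, 128 and 130 without shGFP replicates 2 and 3, and 77 with only the 6 arrays compared. It was 382 with a filter on low values, 481 with trend and robust variance estimates and 359 with array weights.

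HIF1 targets outside glycolysis rose in 18 of 29 cases, 0 fell and 11 did not pass, with 23 higher and 0 lower when adjusted over the list alone (median 0.34, adjusted p = 2.70e-29, adjusted p = 0.0568 with an estimated correlation). In 26 of the 29 the mean was higher in rescue. Glycolysis genes rose in 6 of 23 cases, 0 fell and 17 did not pass, with 11 higher and 1 lower when adjusted over the list alone (median 0.13, adjusted p = 1.74e-08, adjusted p = 0.0629 with an estimated correlation). The glucose transporter Slc2a1 (0.37), named here after its values were seen, lost its call without shFoxk1 replicate 3 (adjusted p = 0.0726) or rescue replicate 3 (0.0647). Phosphofructokinase Pfkl (0.72) lost its call without shFoxk1 replicate 1 (adjusted p = 0.0634) or 3 (0.0726) or rescue replicate 2 (0.0513) or 3 (0.0600), and aldolase Aldoc (0.65) without shFoxk1 replicate 1 (0.0599) or 3 (0.0674). Slc2a3 was called at 0.59 on a probe set that can match other transcripts, and was 0.05 without such probe sets. Of 24 cholesterol synthesis genes 2 rose, 0 fell and 22 did not pass, with 9 higher when adjusted over the list alone (median 0.12, adjusted p = 1.11e-08, adjusted p = 0.182 with an estimated correlation). Fdps (0.28) lost its call without shFoxk1 replicate 1 (adjusted p = 0.0733) or 3 (0.0578) or rescue replicate 3 (0.0645), and Nsdhl (0.33) without shGFP replicate 3 (0.0503), shFoxk1 replicate 1 (0.122) or 3 (0.113) or rescue replicate 2 (0.0910) or 3 (0.09996). In the fatty acid list 2 of 21 rose and 19 did not pass, with 5 higher when adjusted over the list alone (median 0.04, adjusted p = 0.0214, adjusted p = 0.343 with an estimated correlation), and the call was lost without rescue replicate 1 (0.119) or 3 (0.0570). With only the 6 arrays compared, Fdps (adjusted p = 0.0609), Nsdhl (0.104), Pfkl (0.0521) and Lpin1 (0.0620) were not called, nor was Fdps as the mean of its probe sets (0.0613). The phosphatidate phosphatase Lpin1 (0.44) lost its own call without shFoxk1 replicate 1 (adjusted p = 0.0614) or 3 (0.0534).

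TGF-beta and YAP targets lay lower in rescue, with 7 of 25 lower, 0 higher and 18 not past the test, and 13 lower and 2 higher when adjusted over the list alone (median -0.14, adjusted p = 9.60e-12). Ccn2 (-0.69), Ccn1 (-0.37) and Bambi (-0.36) fell, and Crim1 (-0.50) lost its call without shFoxk1 replicate 3 (adjusted p = 0.0512). Ribosome biogenesis genes lay lower as a list (median -0.06, adjusted p = 1.74e-06), with none of 30 called and 3 lower when adjusted over the list alone. Pentose phosphate and nucleotide synthesis genes also lay lower (median -0.06, adjusted p = 0.00733, adjusted p = 0.424 with an estimated correlation), with none of 27 called, and 1 higher and 1 lower when adjusted over the list alone. This call was lost without shFoxk1 replicate 2 (0.0714), with fry (0.0956) and with the filter on low values (0.0534). The ATF4 list lay lower (median -0.05, adjusted p = 0.00804, adjusted p = 0.343 with an estimated correlation), with 1 of 36 lower and 35 not past the test, and 1 lower when adjusted over the list alone. Its call was lost without shFoxk1 replicate 2 (adjusted p = 0.0974) and with fry (0.0720). That member, the cysteine synthesis enzyme Cth (-0.39), lost its call without shFoxk1 replicate 1 (0.0906) or rescue replicate 2 (0.0533) or 3 (0.0925). Matrix proteases and inhibitors rose in 4 of 25 cases, fell in 1 and did not pass in 20, with 8 higher and 2 lower when adjusted over the list alone (median 0.06, adjusted p = 0.0254, adjusted p = 0.343 with an estimated correlation). The stromelysins Mmp10 (0.42) and Mmp3 (0.39) rose. The inhibitor Timp3 (-0.26) fell, and its call was lost without shGFP replicate 2 (adjusted p = 0.0693), shFoxk1 replicate 1 (0.135) or 3 (0.132) or rescue replicate 1 (0.0542), 2 (0.106) or 3 (0.123). The list had adjusted p = 0.0536 with the replicate number as a block, 0.0769 without shFoxk1 replicate 3 and 0.130 without rescue replicate 1. Fibroblast markers rose in 3 of 18 cases and 15 did not pass, with 3 higher when adjusted over the list alone (median 0.05, adjusted p = 0.0169, adjusted p = 0.154 with an estimated correlation, 0.0729 without rescue replicate 3). Lox (0.45) rose, as did Dpt (0.55), whose call was lost without rescue replicate 3 (0.0581). The most abundant fibroblast markers, S100a4 at 14.85 and Vim at 14.45 in rescue, were not called (adjusted p = 0.925 and adjusted p = 0.735). The list of macrophage and blood cell markers had adjusted p = 0.0699, and 0.0440 with the replicate number as a block. With only the 6 arrays compared, the calls of Cth (adjusted p = 0.0805), Timp3 (0.0976), Crim1 (0.0517) and Dpt (0.0563) were lost, and with all probe sets tested that of Timp3 (0.0576). Of 40 lists, 10 were called, 6 higher and 4 lower.

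**Figure D2:**
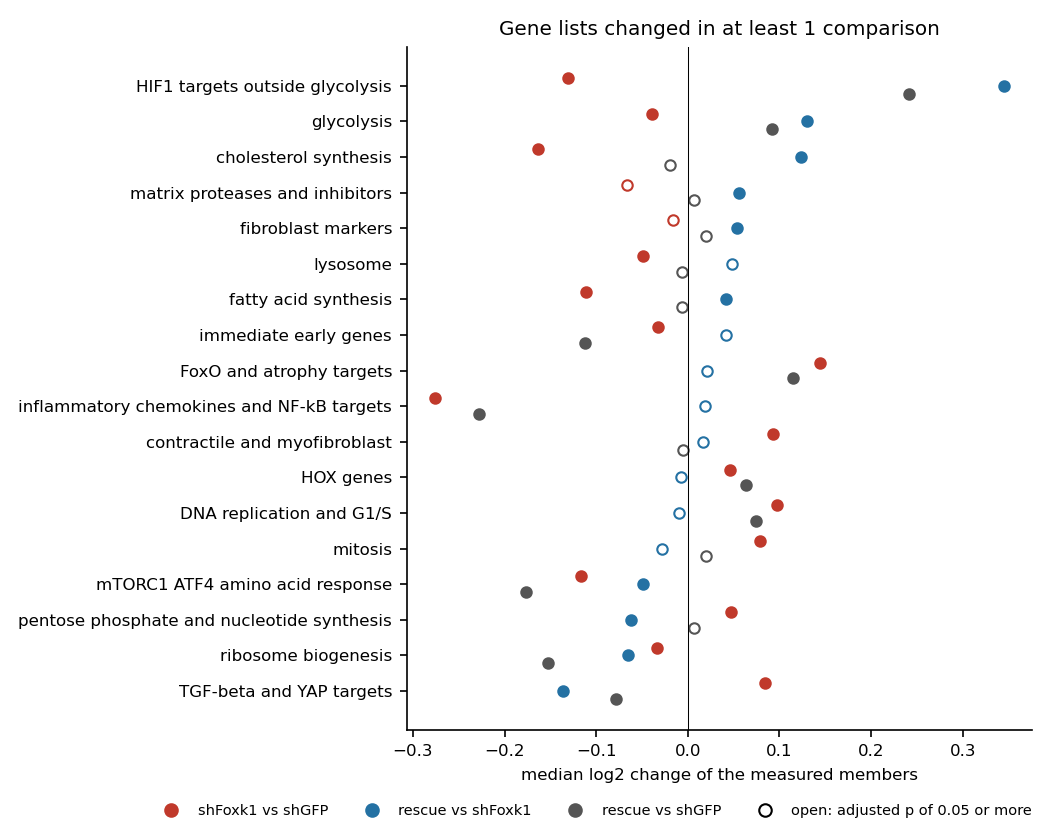
Median log2 change of the members of each gene list (horizontal axis) in shFoxk1 against shGFP, rescue against shFoxk1 and rescue against shGFP; filled points have a camera adjusted p under 0.05 and open points do not. The HIF1 list stood at -0.13, 0.34 and 0.24 in these comparisons.

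Some knockdown changes turned back in the samples labelled rescue. Of 86 genes called both in the knockdown and in rescue against shFoxk1, 81 moved in opposite directions. In 29 genes a rise was followed by a fall, including Bmp4 (1.23 then -0.83), Akap12 (0.93 then -0.60), Heca (0.87 then -0.36) and Tagln (0.87 then -0.71). In 52 a fall was followed by a rise, including Adm (-0.88 then 1.17), the semaphorin gene Sema7a (-0.77 then 0.35), Mmp10 (-0.72 then 0.42), Gch1 (-0.71 then 0.42), which makes the cofactor tetrahydrobiopterin, and Tcim (-0.70 then 0.48). Ptx3 (1.54 then -0.62) lost the second call without shGFP replicate 2 (adjusted p = 0.0722), shFoxk1 replicate 1 (0.162), 2 (0.0514) or 3 (0.164) or rescue replicate 2 (0.144) or 3 (0.134) or with all probe sets tested (0.0540), and Dpt (-0.78 then 0.55) without rescue replicate 3 (adjusted p = 0.0581). Independent lists of these sizes would share 1.22 and 3.06 such genes. Of the other genes called in both, 3 rose in both, against 2.66 of independent lists, and 2 fell in both, against 1.40. In 20 simulations that kept the knockdown changes and placed the rescue changes on random genes, groups sharing the shFoxk1 arrays gave 4.05 reversed genes on average and 7 at most. Noise drawn independently for each array and gene, with the shFoxk1 arrays shared, thus did not give 81. A deviation common to the shFoxk1 arrays was not simulated, and the 3 arrays cannot be divided into parts of at least 2. Part of the excess may come from such a deviation. With no effect in any group, simulations gave at most 0 reversed genes, a count that tests little because almost no gene passes the adjustment there. Of the 81 genes, 58 were not called against shGFP in rescue, 14 were still called in the direction of the knockdown and 9 were called past the shGFP level.

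**Figure D3:**
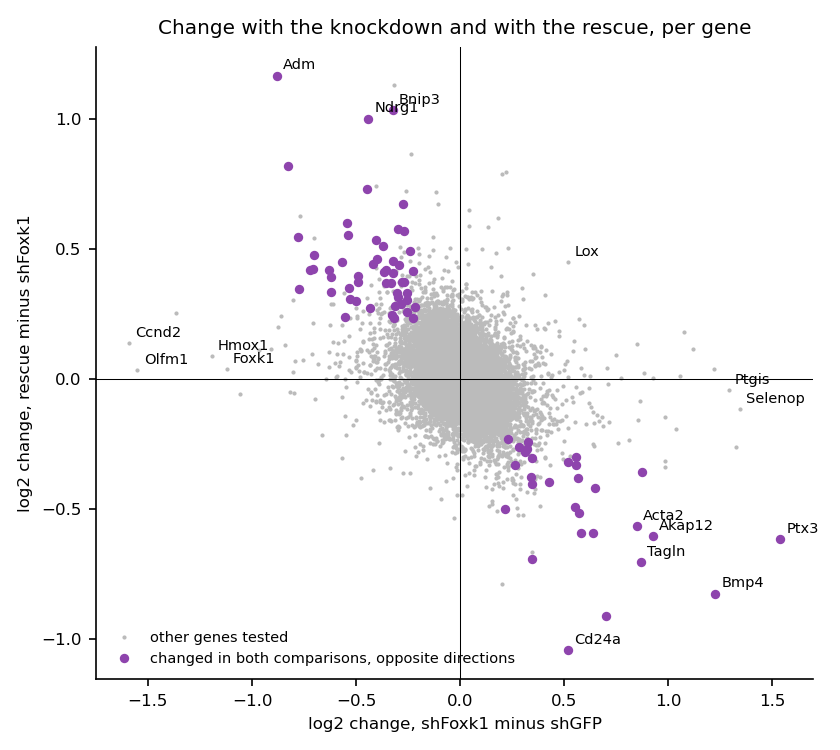
Log2 change of each gene in shFoxk1 against shGFP (horizontal axis) and in rescue against shFoxk1 (vertical axis); each point is a gene, and the 81 genes called in both with opposite signs are purple. Shared shFoxk1 arrays tilt the cloud downward by themselves, with a simulated correlation of -0.499 for unchanged groups and -0.416 observed.

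Other knockdown genes were still called against shGFP in rescue. Ccnd2 (-1.45 against shGFP in rescue), Olfm1 (-1.52), Hmox1 (-1.11), Ptgis (1.25) and Selenop (1.23) remained called. Of the 876 knockdown genes, 491 (56.1%) were called in the same direction in rescue against shGFP, 231 higher and 260 lower, while 376 were not called there and 9 were called the opposite way. Both comparisons share the shGFP arrays. Simulated groups in which each knockdown change returned in full gave the same sign in 55.7% of knockdown genes, against 94.4% observed. They gave at most 0 same-direction calls in 20 simulations. That count tests little, because rescue and shGFP did not differ in any gene there and the adjustment then passes almost none. The same limit holds for simulations with no effect, which gave at most 1. Independent lists would share 10.2 higher and 11.9 lower genes, and part of the excess may come from the shared arrays. Of the 11 HIF1 list members called in the knockdown, 8 reversed. Of 16 such members of the inflammatory list 1 reversed and 13 were still called against shGFP, and of 10 such members of the ATF4 list 0 reversed and 9 were still called. Across all genes, which are not independent replicates, the knockdown and rescue changes correlated at -0.416 (jackknife SE over arrays 0.122), where simulated unchanged groups gave -0.499. Their covariance was -0.00600, against -0.00299 in the simulation, a difference of -0.00301. The reversed count of 81 was 51, 48 and 47 without shGFP replicates 1, 2 and 3, 38 and 33 without shFoxk1 replicates 1 and 3, and 52 and 45 without rescue replicates 2 and 3. It was 161 with a filter on low values, 173 with trend and robust variance estimates, 143 with array weights and 0 with a minimum change of 1.

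**Figure D4:**
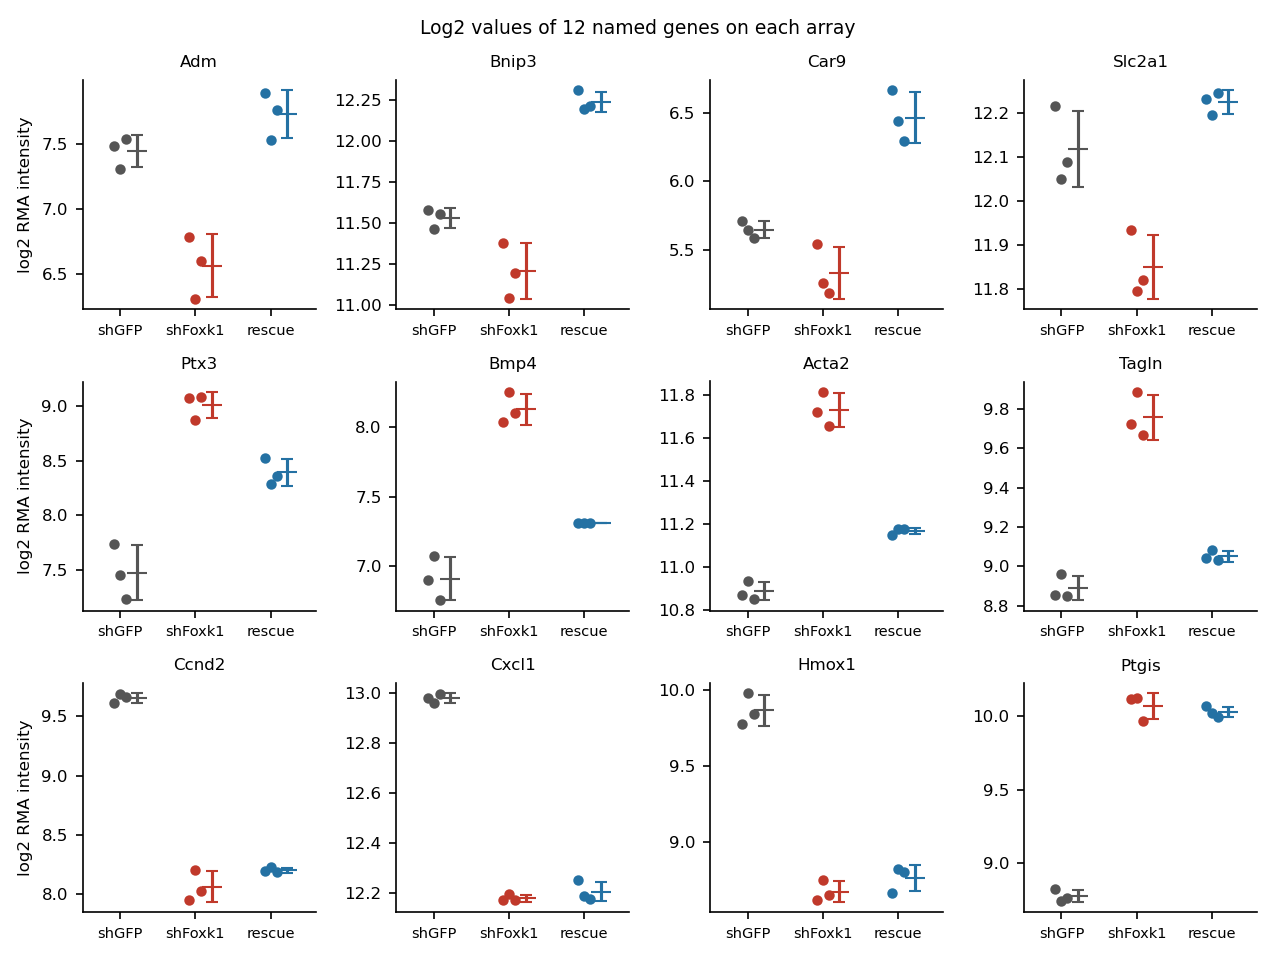
Log2 level of 12 genes on each array (points) with the mean ± SD of 3 arrays per group (bars), a panel per gene with its own vertical range. Adm, Bmp4 and Tagln moved one way in shFoxk1 and back in rescue, whereas Ccnd2 (9.65, 8.06 and 8.20), Cxcl1 (12.98, 12.18 and 12.20), Hmox1 and Ptgis stayed near their shFoxk1 level.

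The comparison of rescue with shGFP asks how far cells with the hairpin and added Foxk1 still differed from control cells. Armcx4 (1.26, SE 0.11), H19 (1.26, SE 0.08), Ptgis (1.25, SE 0.05), Thbs2 (1.23, SE 0.09) and Selenop (1.23, SE 0.07) were highest above the control, followed by Lrrc17 (1.02), the cyclin-like gene Ccng2 (0.99), Cxxc5 (0.98) and Lox (0.97). Olfm1 (-1.52, SE 0.08), Ccnd2 (-1.45, SE 0.06), Sema5a (-1.11, SE 0.10), Hmox1 (-1.11, SE 0.07) and Foxk1 (-1.08, SE 0.08, adjusted p = 8.47e-05) were furthest below it. Slco4a1 (-0.88), Galnt3 (-0.87), the calcification inhibitor Mgp (-0.86), cyclooxygenase 2 gene Ptgs2 (-0.85) and Plcg2 (-0.85) were lower as well. Nfatc4 was called at 1.07, and was 0.03 without probe sets that can match other transcripts. In all, 1042 genes were called (5.04%), 516 higher and 526 lower, with 14 changed at least 2-fold. Groups stood apart for 22.3% of genes, where chance gives 10%. Among 17417 dimmer probe sets, 445 were called although the gene's brightest was not, 396 of them lower in rescue. The count of 1042 fell to 578, 567 and 587 without shGFP replicates 1, 2 and 3 and to 692 and 587 without rescue replicates 2 and 3. It was 1614 with a filter on low values and 1640 with trend and robust variance estimates.

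Several lists were low in both the knockdown and rescue against shGFP. In the ATF4 response, 15 of 36 genes were lower, 0 higher and 21 not past the test, with 25 lower and 1 higher when adjusted over the list alone (median -0.18, adjusted p = 1.99e-18). Sesn2 (-0.64), Psph (-0.49) and Slc7a11 (-0.44) were among them. Inflammatory and NF-kB genes were lower in 14 of 28 cases, higher in 1 and not past in 13, with 20 lower and 3 higher when adjusted over the list alone (median -0.23, adjusted p = 4.96e-14). Cxcl1 (-0.78), Ptgs2 (-0.85), Ccl7 (-0.58) and Ccl2 (-0.55) were lower, and Cxcl12 (0.33), again named after its values were seen, was higher. Ribosome biogenesis genes were lower in 6 of 30 cases and not past in 24, with 17 lower when adjusted over the list alone (median -0.15, adjusted p = 1.26e-11). Examples were Rrp12 (-0.30) and Myc (-0.22), and both lost their call without shGFP replicate 1 (adjusted p = 0.135 and 0.125), 2 (0.123 and 0.0712) or 3 (0.0771 and 0.0702) or rescue replicate 1 (0.0513 and 0.0616), 2 (0.0951 and 0.0896) or 3 (0.141 and 0.0771), and Rrp12 also without shFoxk1 replicate 3 (0.0609) and Myc with only the 6 arrays compared (0.0513). Immediate early genes were lower in 3 of 25 cases, higher in 1 and not past in 21, the same numbers as when adjusted over the list alone (median -0.11, adjusted p = 0.00174, adjusted p = 0.0932 with an estimated correlation). Nr4a1 (-0.38) and Phlda1 (-0.27) were lower and Etv5 (0.36) higher, the last not called as the mean of its probe sets (adjusted p = 0.378). TGF-beta and YAP targets, which lay higher in the knockdown, were lower here in 8 of 25 cases, higher in 4 and not past in 13, with 10 lower and 6 higher when adjusted over the list alone (median -0.08, adjusted p = 0.0119, adjusted p = 0.132 with an estimated correlation, 0.102 with the filter on low values). Bambi (-0.64) and Pmepa1 (-0.54) were lower and Fstl1 (0.52) higher.

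HIF1 targets outside glycolysis stood above the control in rescue, with 14 of 29 higher, 1 lower and 14 not past the test, and 18 higher and 1 lower when adjusted over the list alone (median 0.24, adjusted p = 3.12e-13, adjusted p = 0.132 with an estimated correlation). Lox (0.97), Bnip3 (0.71), P4ha2 (0.60), Mxi1 (0.52) and Fam162a (0.40) were higher and Stc2 (-0.47) was lower, with Bnip3 and Stc2 named here after their values were seen. Glycolysis genes were higher in 6 of 23 cases, lower in 2 and not past in 15, with 10 higher and 3 lower when adjusted over the list alone (median 0.09, adjusted p = 0.00220, adjusted p = 0.214 with an estimated correlation). Aldoc (0.69), Pfkl (0.60) and triosephosphate isomerase Tpi1 (0.28) were higher. The members that were lower were Pfkfb3 (-0.37), a regulator of phosphofructokinase, and the lactate transporter Slc16a1 (-0.23), both named after their values were seen. Pfkfb3 lost its call without shGFP replicate 1 (adjusted p = 0.0991) or 2 (0.0777) or rescue replicate 2 (0.0670) or 3 (0.0870) and as the mean of its probe sets (0.310), and Slc16a1 without shGFP replicate 1 (0.119), 2 (0.0685) or 3 (0.0971) or rescue replicate 1 (0.0622) or 2 (0.0977) and as that mean (0.119). Slc2a3 was called at 0.63, and was -0.06 without probe sets that can match other transcripts. DNA replication genes were higher in 2 of 33 cases and not past in 31, with 3 higher when adjusted over the list alone (median 0.07, adjusted p = 0.000599, adjusted p = 0.132 with an estimated correlation). Rpa2 (0.21) lost its call without shGFP replicate 1 (adjusted p = 0.0577), 2 (0.0527) or 3 (0.0704) or rescue replicate 3 (0.0511), and Slbp (0.19) without shGFP replicate 1 (0.123), 2 (0.0777) or 3 (0.0882), shFoxk1 replicate 1 (0.0534) or rescue replicate 1 (0.0579), 2 (0.0768) or 3 (0.10002). As the mean of all probe sets of a gene, Rpa2 (adjusted p = 0.0664) and Slbp (0.193) were not called, nor was Slbp with only the 6 arrays compared (0.0532). FoxO and atrophy targets were higher in 5 of 20 cases and not past in 15, with 8 higher and 1 lower when adjusted over the list alone (median 0.12, adjusted p = 0.000599, adjusted p = 0.152 with an estimated correlation), including Ccng2 (0.99) and Pik3ip1 (0.64). HOX genes were higher in 4 of 32 cases and not past in 28, with 7 higher when adjusted over the list alone (median 0.06, adjusted p = 0.0293, adjusted p = 0.132 with an estimated correlation), including Hoxb6 (0.38) and Hoxb2 (0.25). The HOX call was lost without shGFP replicate 1 (adjusted p = 0.0505) or rescue replicate 1 (0.0554). Of 40 lists 10 were called, 5 higher and 5 lower, and no marker list was among them. With an estimated correlation, the calls that held were the inflammatory (adjusted p = 0.00419) and ATF4 (0.0371) lists in the knockdown, the TGF-beta (0.0107) and ribosome biogenesis (0.0213) lists in rescue against shFoxk1, and the ATF4 (0.00810), inflammatory (0.00389) and ribosome biogenesis (0.00389) lists in rescue against shGFP.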

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

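The tests of the second probe sets below, and the genes given as examples, were chosen after the result was seen. Probe sets without a gene symbol were called 54 times in shFoxk1 against shGFP, 11 times in rescue against shFoxk1 and 66 times in rescue against shGFP, of 6948. The largest knockdown change among them was 2.61 (adjusted p = 4.98e-06), and what it measures is not given in the sources used here. A dimmer Hif1a probe set fell by 1.04 in the knockdown (adjusted p = 0.00345), while the brightest differed by -0.06 (adjusted p = 0.825 over all probe sets). The remaining Hif1a probe sets were not called either, at -0.16 (adjusted p = 0.237) for the second brightest and 0.13 (adjusted p = 0.278) for the dimmest. The probe set that fell did not return, and stood at -1.47 in rescue against shGFP (adjusted p = 0.000447).

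The Hif1a case was 1 of many. Second probe sets were called where the gene's brightest was not 294 times in the knockdown (69 higher, 225 lower), 12 times in rescue against shFoxk1 (8 higher, 4 lower) and 445 times in rescue against shGFP (49 higher, 396 lower). A bias of dim probe sets toward lower calls would show in genes with a single probe set too, and at similar levels 53.9% of called genes of that kind were lower (83 of 154) against 76.5% of the 294. The difference of 22.6 points was 8.58 without shFoxk1 replicate 2 and 38.9 without shFoxk1 replicate 3, so this bias stays open. RNA of a different length could lower some probe sets of a gene. The actin 3′ minus 5′ difference was only 0.018 higher on the arrays with the hairpin, shFoxk1 and rescue together, than in shGFP. Actin is a short transcript, however, and leaves this open. An effect of Foxk1 on transcript ends would be expected to return with Foxk1, and the 225 probe sets returned by a median share of -0.0299, but no Foxk1 probe set was called higher in rescue, so this cannot be told apart from an effect of the hairpin.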

How the results depend on the processing

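Leaving out probe sets ending in _x_at or _s_at, and median centring for the lists, were chosen after seeing the data; the other settings were planned. The main counts were 876, 197 and 1042 genes in shFoxk1 against shGFP, rescue against shFoxk1 and rescue against shGFP, and 81 reversed genes. They were 1501, 382, 1614 and 161 with a filter on low values, which tests fewer genes, and 1530, 481, 1640 and 173 with trend and robust variance estimates. Array weights gave 1541 and 359 for the knockdown and rescue against shFoxk1 and 143 reversed genes, a minimum log2 change of 1 gave 16, 5, 14 and 0, and only the 6 arrays compared gave 77 for rescue against shFoxk1. Leaving out 1 array gave 460 to 943, 74 to 219, 567 to 1026 and 33 to 87 reversed genes. Foxk1 differed between rescue and shFoxk1 by -0.052 to 0.11 in these fits. The change of Foxk2, rescue vs shFoxk1, was -0.0465 to 0.0559 in them and -0.00114 after median centring. In the knockdown, the other Foxk1 probe sets gave -0.25 and -0.10. Camera with an estimated correlation called 2, 2 and 3 lists in place of 16, 10 and 10. Without probe sets ending in _x_at or _s_at, signs turned in the knockdown for Nfatc4 (-0.021), Acta2 (-0.13) and Ppat (-0.15), and in rescue against shGFP for Slc2a3 (-0.058). With the mean of a gene's probe sets they turned for Ppat, shFoxk1 vs shGFP (-0.00475), and Aurka, shFoxk1 vs shGFP (0.00054). The replicate block gave 1074, 244, 1223 and 109. Its calls held 829 of the 876, 167 of the 197 and 965 of the 1042 genes of the main fit. Among the lists and named genes, it ended the calls of the matrix protease list in rescue against shFoxk1 (adjusted p = 0.0536) and of Npc1 in the knockdown (adjusted p = 0.0582). It gave the macrophage and blood cell marker list a call (adjusted p = 0.0440). Where the construction does not show it, the cause was not tested. RMA compresses small differences near the background, which limits the fold changes of dim probe sets.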

Other observations

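The matrix genes and Cdkn1a named here, the tests of the kept changes and the reading of the HIF1 pattern as an effect of added Foxk1 were chosen after the result was seen. Of the collagen and matrix genes, 9 were called in the knockdown. Of these, 5 reversed in rescue against shFoxk1, and 4 of the 9 were still called in the knockdown's direction against shGFP. Of the 5 reversed genes, 3 fell and then rose, and 2 rose and then fell. Among the former, Col6a3 (-0.63) and Dcn (-0.28) fell in the knockdown and then rose (0.42 and 0.67). Col6a3 lost the second call without shFoxk1 replicate 3 (adjusted p = 0.0578), and Dcn lost the first as the mean of its probe sets (adjusted p = 0.103). Col6a2 also fell and then rose. It lost the first call without shGFP replicate 1, 2 or 3 or shFoxk1 replicate 1 or 3. The second call was lost in the same fits, without rescue replicate 2 or 3 and with all probe sets tested. Thbs1 lost its knockdown call without shGFP replicate 2 or 3 or shFoxk1 replicate 1 or 3, and as the mean of its probe sets. Col5a2 lost its call in rescue against shFoxk1 without shFoxk1 replicate 1 or rescue replicate 3. Cdkn1a, a p53 target, fell (-0.54) and rose again (0.55). The collagen and matrix list as a whole was not called in the knockdown (adjusted p = 0.837) or in rescue against shFoxk1 (adjusted p = 0.176).

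HIF1 targets were higher in rescue than in shFoxk1, with a median of 0.34, though the list's call was lost with an estimated correlation (adjusted p = 0.0568). A single aberrant array is argued against by the leave-outs, whose lowest median was 0.32. A bias of normalization that depends on level alone is argued against by random lists of matched level, of which 0 reached 0.34 (highest 0.0876). Random genes need not move together as members of a list do, so these lists do not test other biases of normalization. A batch that moves all arrays of a replicate number alike cannot make this difference, because each number holds 1 array of each group. The changes within numbers, 0.34 at the lowest, add no test of it, since that balance fixes their outcome. An effect of added Foxk1 could explain the rise from a knockdown median of -0.13, but rescue passed the control (0.24). In neither of these comparisons with shGFP was the list called with an estimated correlation. No Foxk1 probe set was called higher in rescue. An effect of added Foxk1 therefore cannot be told apart from a difference in oxygen or density of the cultures.

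Of 876 knockdown genes, 491 were still called in the same direction in rescue against shGFP. A large return that the test lacked power to see is argued against, since the median return over all 876 genes was 0.226 of the change, and 0.242 at the highest with 1 array left out. Whether all genes returned by the same share stays open. Of the 876 genes, 195 departed from a common share (adjusted p under 0.05) at the share with the fewest, 0.15. The lowest number with 1 array left out was 126, without shFoxk1 replicate 1, and it was 135 without shFoxk1 replicate 3 and 133 without rescue replicate 2 or 3. The 876 genes were chosen on the same shFoxk1 and shGFP arrays, which can itself make departures at 0.15, and a uniform return was not simulated. At a share of 0.5, where choice and departure are uncorrelated, 405 departed, but a common return by another share would give departures there too. Effects of the hairpin or the cell line, which rescue shares, could keep changes in place, and this cannot be told apart from a partial return of Foxk1, because both rescue and shFoxk1 carry the hairpin and the level of the added Foxk1 is not known.

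Regrouping the arrays of 2 groups gives 10 splits, too few for a share under 0.05. The real split was the highest, 1 of 10, in each comparison, for genes (876, 197 and 1042, highest other 0) and for lists (16, 10 and 10, highest other 6, 4 and 6). In rescue against shFoxk1, splits parting as many same-numbered pairs as the real one gave at most 0 genes and 2 lists, and those parting fewer at most 0 genes and 4 lists. For reversed genes, 4 of 100 groupings of all 9 arrays reached 81, the real grouping being 1 of these 4, and the highest had 416. In the splits with 416 and 327 genes the 3 shGFP arrays form the middle group, the one in both comparisons, which points to a structure of the samples that sets shGFP apart. The split with 90 is the real groups with rescue in the middle. In 3 more splits the shGFP arrays were together outside the middle group, and these gave 0.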
